A study of Mus musculus with 4 samples.

How the data were processed

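Immune cells that carried CD45 and lacked CD19, a gate that keeps leukocytes and leaves out B cells, were sorted from omental tumours of wild-type mice given KPCA cells, a mouse ovarian cancer line, per the labels. Cells of 3 mice per treatment group were pooled, tagged with TotalSeq-B hashtag antibodies and run on the 10x Genomics droplet platform, per the labels' protocols. The labels describe 2 gene expression libraries, each with a hashtag library. The first held cells of mice given IFNg (interferon gamma) or beta-glucan, a yeast cell wall sugar polymer, and the second held cells of mice given PBS (the vehicle) or both agents.

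The deposited values are raw UMI counts per gene and per hashtag in each cell barcode, in 1 matrix for the whole series. Per the file headers they were made with Cell Ranger 7.0.0, and the submitters' processing notes name the mouse build mm10, Cell Ranger and Seurat. The settings of alignment and cell calling are not given in the sources used here. The matrix held 24977 cells, 32285 genes, 6 hashtags and 277468912 gene UMIs. The lowest cell had 500 UMIs, the median cell 8587 UMIs and 2776 genes, and the highest cell 104645 UMIs. No cell annotation was used, so cell classes were rebuilt from the counts and may differ from those of the authors.

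Cells were assigned by hashtag. In 9079 cells (36.35%), at least 90% of the hashtag UMIs came from hashtags 8 and 9, and in 15445 cells (61.84%) from hashtags 3 and 5. A further 426 cells were mixed and 27 had no hashtag signal. In the feature list hashtag 8 is named WGP_IFNg and hashtag 9 is named PBS. This pair matches the library of PBS or combination cells, with WGP read as the beta-glucan because the only label that pairs IFNg with another agent is the combination. Hashtags 3 and 5 are named PBS and B-1. These names do not match the IFNg or beta-glucan library, so their cells were assigned to no treatment and entered no comparison. Hashtags 1 and 7, named WGP and IFNg, had 2666 and 10152 UMIs in all and at most 18 and 32 in a cell, so no cell was assigned to them. A cell was called for a hashtag when it had at least 10 hashtag UMIs and at least 70% from that hashtag. A cell with at least 25% from each of 2 hashtags was a hashtag doublet and was removed. In the 8 and 9 pair the median share of the larger hashtag was 74.35%, against 91.26% in the 3 and 5 pair. The rule therefore removed 4746 cells (52.27%) of the first pair as doublets and 1953 cells (12.64%) of the second.

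Cells were kept with at least 500 UMIs, at least 300 genes and at most 10% mitochondrial UMIs, which 23618 cells passed. Scrublet, in scanpy 1.11.5, marked 1300 cells (8.42%) of the 3 and 5 pair as doublets and 0 of the 9079 cells of the 8 and 9 pair, so it did not work in the pair that was compared. There only the hashtag rule removed doublets, and doublets of cells with the same hashtag stayed. The 16477 remaining cells were clustered on 2000 variable genes, 30 principal components and 15 neighbours by the Leiden method at resolution 1.0 with seed 0, in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and igraph 0.11.9. Each of the 27 clusters took the class with the highest mean log2 CPM (counts scaled to a common library total, plus 5) of its markers relative to the mean of all clusters. At least 3 of the markers had to be detected in at least 25% of the cells and lie at least 1 log2 unit above that mean. A cluster stayed unnamed where its 10 leading genes held more markers of another class, where 2 classes scored within 0.25, or where its UMI counts were low and its leading genes held no marker of the class. Unnamed clusters held 2.18% of the combination cells and 2.25% of the PBS cells. The marker lists were fixed before the data were examined, and the scoring rule was set afterwards. In the alternatives below a cluster took the class of over 50% of its cells.

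The comparison was of the combination (hashtag 8, 1977 cells) with PBS (hashtag 9, 1915 cells). Each group was 1 pool of 3 mice that cannot be told apart, so there is no replicate, and no p-value, standard error or test between groups was computed. Counts were summed per class and group in classes with at least 100 cells in each group, and CPM was taken over all genes. CPM intervals are exact Poisson 95% intervals, intervals of ratios are exact conditional binomial 95% intervals, and shares of cells have exact Clopper-Pearson 95% intervals. Differences of shares have Newcombe 95% intervals. All of them cover counting error only and leave out differences between mice. The intervals of CPM and of ratios also treat UMIs of the same cell as independent. Where a group had under 3 counts, the ratio was computed against 3 counts. A gene was called higher or lower when the ratio of CPM reached 1.5 in either direction, among genes with at least 100 counts over both groups.

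These gene lists were fixed before the data were examined: IFN-gamma response, type I interferon response, MHC class II, MHC class I processing, IL27 axis, dectin-1 and NF-kB inflammatory, alternative activation, resident cavity and omental macrophage, complement and phagocytosis, lipid-associated macrophage, coagulation, hypoxia and glycolysis, chemokines, cytotoxic effector, T cell inhibitory receptors, naive and memory T cell, regulatory T cell, helper T cytokines, cell cycle, dissociation stress, mitochondrially encoded, and genes that differ between female and male animals. For each list, members with at least 50 counts were measured. The list's median log2 ratio was placed as a percentile among 10000 random lists of the same size matched on mean expression. This percentile describes these libraries and is not a test between treatments. Genes were named by a rule fixed before the data were examined. Any list member could be named, and beyond the lists the 10 genes with the highest and the 10 with the lowest ratio per class, with at least 100 counts, a UMI in at least 5% of the cells of the group with more and a ratio of at least 1.5. Gene models without a symbol of their own, immunoglobulin and T cell receptor segments, haemoglobin and mitochondrial genes were left out of the names. Shares of cells with a UMI were compared after each cell was thinned to 1000 UMIs.

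The steps from counts to ratios were tested on simulated data drawn from the summed counts of each class. With 10246 genes in the macrophage-like step, 98% of the genes raised 2-fold passed 1.5-fold, and 0.41% of the unchanged genes did. In the neutrophil-like step (5364 genes) these shares were 100% and 0.91%, and in the T cell-like step (9158 genes) 100% and 0.56%. The simulated counts were Poisson draws around a mean per gene, with no spread between cells, mice or pools. These shares therefore check the computation and are not error rates of the 1.5-fold rule in the real pools.

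Alternatives fixed before the data were examined were other cell filters, doublets kept, Leiden resolutions of 0.5 and 2.0, clustering without the interferon and MHC genes, a stricter hashtag rule (90% of at least 20 UMIs), TMM scaling from edgeR 4.0.16 in R 4.3.3, equal weight for each cell, totals without mitochondrial and ribosomal genes, other count minimums, and thinned cells. Others were added after the data were seen: the larger hashtag of the pair for every cell, the 8 and 9 pair clustered alone, removal of the highest 7% of Scrublet scores in that pair, and macrophage-like cells without cluster 0. Gene positions are from the GENCODE M21 annotation of GRCm38, the assembly that mm10 names, matched by Ensembl ID. Of the 32285 genes, 32158 matched, and so did 102 of the 102 genes looked up for the text.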

Results

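Single-cell transcriptomes were collected from immune cells of omental tumours in mice that carried the KPCA ovarian cancer line. The omentum is a fatty fold of the abdominal lining to which ovarian cancer spreads. The series asks how activation of myeloid cells in the abdominal cavity acts on this cancer and whether the cytokine IL27 takes part, as its title states. Mice received PBS, IFNg, beta-glucan, or beta-glucan with IFNg. IFNg is the cytokine that activates macrophages, and beta-glucan is a fungal cell wall polymer that binds the receptor dectin-1. The only contrast that the hashtag names and labels define together was the combination of both agents against PBS, 1 pool of 3 mice each, with both pools in the same library. After the filters, the combination pool held 1977 cells with 35021921 gene UMIs and a median of 15997 UMIs per cell. The PBS pool held 1915 cells with 29644208 UMIs and a median of 12542. There are no replicates, so differences between the pools were not set against a spread between mice, and the intervals given cover counting error only.

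**Figure D1:**
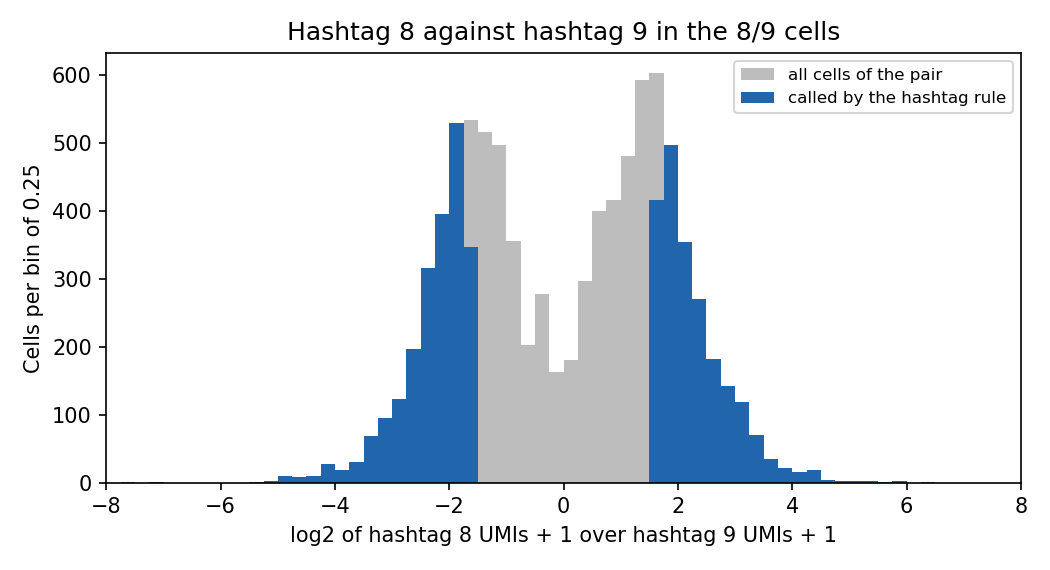
Histogram of the log2 ratio of hashtag 8 (combination) to hashtag 9 (PBS) UMIs, each plus 1, over the 9079 cells of this pair, in bins of 0.25. Blue bars show cells called for 1 of the hashtags and grey bars those left out, and the cut of the rule runs through both peaks, so the 4746 cells called doublets include cells of each peak.

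The makeup of the immune infiltrate was compared first. Macrophage-like cells made up 44.6% of the combination pool (95% interval 42.4 to 46.8) and 28.7% of the PBS pool (26.7 to 30.8). Monocyte-like cells, the precursors that enter from blood, made up 1.82% (1.28 to 2.51) and 3.39% (2.63 to 4.31). Plasma cell-like cells, which secrete antibody, made up 2.58% (1.93 to 3.38) of the combination pool and 5.59% (4.60 to 6.71) of the PBS pool. T cell-like cells made up 32.7% (30.7 to 34.8) and 38% (35.8 to 40.2), neutrophil-like cells 8.04% (6.88 to 9.33) and 10.9% (9.50 to 12.3), and NK cell-like cells 2.02% (1.45 to 2.75) and 4.39% (3.51 to 5.40). The rarer dendritic classes were conventional type 1 dendritic-like cells (0.708% and 1.57%), type 2 (2.68% and 3.34%), mature (1.97% and 1.15%) and plasmacytoid (0.708% and 0.783%).

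These shares depended on which cells the hashtag rule called. It called 74.1% of the macrophage-like cells of the pair but 60.0% of the T cell-like, 39.7% of the NK cell-like, 19.9% of the monocyte-like and 19.4% of the neutrophil-like cells. When every cell went to the larger of its 2 hashtags (4420 and 3701 cells), macrophage-like cells made up 25.8% and 20.2%, monocyte-like cells 5.88% and 8.86% and plasma cell-like cells 4.89% and 6.43%, in the same direction as above. T cell-like cells (28.8% and 27.0%), neutrophil-like cells (21.6% and 21.3%) and NK cell-like cells (4.39% and 4.35%) then changed direction, so no difference is claimed for these 3 classes. Under a stricter rule of 90%, which kept few cells, the monocyte-like share also changed direction, by 1.71 percentage points, and the macrophage-like difference was 4.15 points (-6.55 to 14.7).

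**Figure D2:**
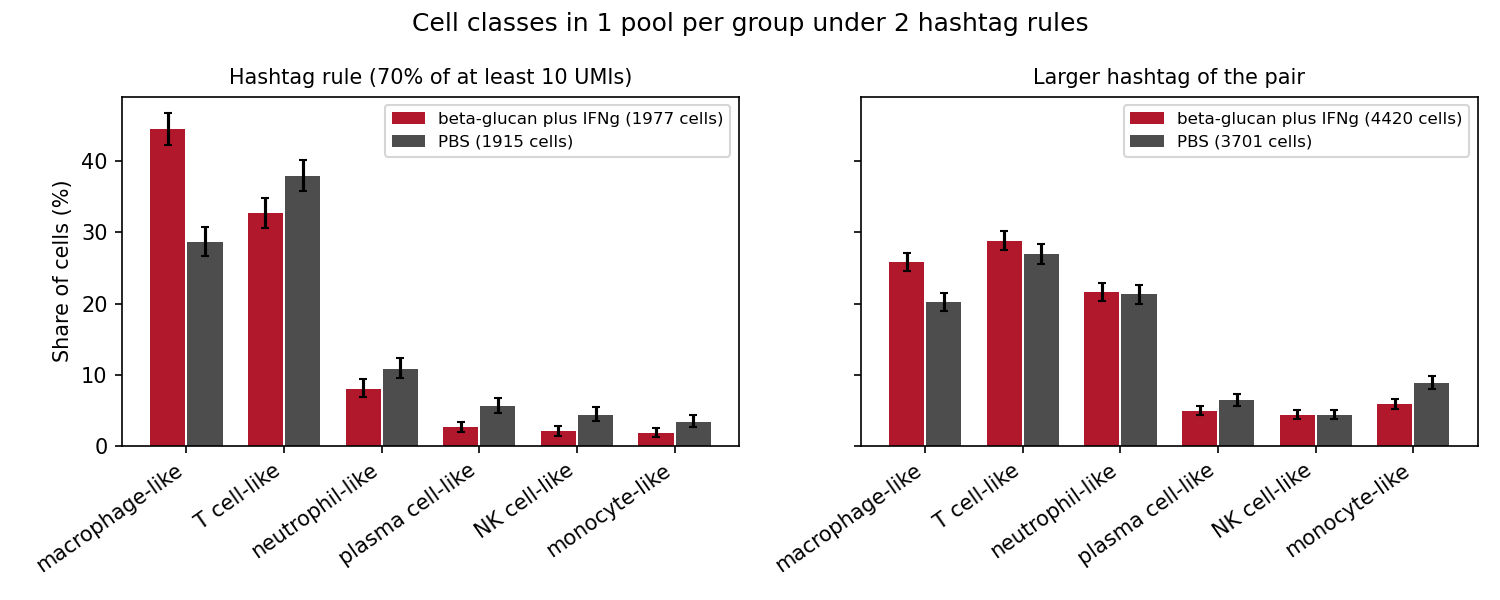
Share of cells (%) of 6 classes in the combination pool (red) and the PBS pool (grey), by the hashtag rule on the left and by the larger hashtag on the right, with exact 95% intervals over cells. The macrophage-like share was above that of PBS under both rules (44.6% and 28.7% on the left, 25.8% and 20.2% on the right), whereas the T cell-like order changed.

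Macrophage-like cells of the combination pool had far lower levels of the genes of large cavity macrophages than those of the PBS pool. Gata6, the transcription factor of this population, was at 1.37 CPM (0.884 to 2.02) with the combination and 30.8 CPM (27.4 to 34.5) with PBS. Prg4, which encodes the lubricant lubricin, was at 6.99 and 488 CPM, Alox15, a lipoxygenase, at 5.08 and 395 CPM, and Selp, which encodes P-selectin, at 3.17 and 121 CPM. Much of this difference lay in cluster 0, described below, without which the PBS cells were at 3.79 CPM for Gata6 and 60.0 CPM for Prg4. In contrast, Apoe, the lipid carrier, was 2.45 times as high with the combination (9206 and 3764 CPM), and the MHC class II genes H2-Ab1, H2-Eb1 and Cd74, which present peptides to helper T cells, were 1.61, 1.69 and 1.54 times as high (1.33, 1.37 and 1.28 times without cluster 0, described below, so under 1.5-fold). The class held 881 combination cells (median 20394 UMIs, 18307790 in all) and 550 PBS cells (median 16882.5, 9751011 in all). Of 10235 genes with at least 100 counts, 557 were at least 1.5-fold higher with the combination and 623 at least 1.5-fold lower.

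Of the 15 measured genes of the resident cavity and omental macrophage list, 9 were at least 1.5-fold lower and 3 higher, with a median log2 ratio of -1.39, below all 10000 matched random lists. The 3 higher members were Lyve1 (44.2 and 14.0 CPM), Vsig4 (24.1 and 7.79 CPM) and Cbr2 (44.9 and 18.0 CPM), known from tissue macrophages around vessels and in serous linings. Vsig4 was detected in only 2.72% of the combination cells, and its ratio ranged from 1.35 to 4.50 over the settings. The scavenger receptor gene Marco was at 102 and 266 CPM. Most macrophage-like cells of both pools lay in cluster 3 (764 and 389 cells). Cluster 0, however, held 80 PBS cells and 0 of the 881 combination cells, which allows a share of up to 0.341%. Without cluster 0 the list's median was -0.48, still below all random lists, with Prg4 at 60.0 CPM, Alox15 at 68.3 CPM, Selp at 25.5 CPM, Marco at 142 CPM and Gata6 at 3.79 CPM in the PBS cells. Gata6 then rested on only 25 combination and 29 PBS UMIs, in 1.93% and 2.13% of the cells. Alox15 was detected in 5.79% and 10.9%, so few cells carried these genes there. The apoptotic cell receptor gene Timd4 changed direction, with a ratio of 0.41 over all cells and 2.84 without cluster 0. The latter ratio rests on few cells, since Timd4 was detected there in 3.06% and 2.55%. Ptgis, Ltbp1 and Ofcc1 were among the 10 named genes with the lowest ratios (0.0113, 0.0172 and 0.0075), and without cluster 0 these were 0.130, 0.169 and 0.0607.

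In the hypoxia and glycolysis list 8 of 14 genes were lower and 0 higher (median -0.62, below all random lists). Egln3, an oxygen-sensing hydroxylase induced by low oxygen, was at 39.3 and 212 CPM, the growth factor gene Vegfa at 40.7 and 95.2 CPM, the glucose transporter gene Slc2a1 at 82.5 and 155 CPM, and Ldha, which makes lactate, at 342 and 528 CPM. Under the stricter hashtag rule (97 and 80 cells) only 1 of the 14 was lower (median -0.32), and Vegfa (0.72), Slc2a1 (0.77) and Ldha (0.81) did not pass 1.5-fold. In the coagulation list 8 of 12 were lower and 1 higher (median -0.90). Thbs1 was at 177 and 1064 CPM, Serpine1, the plasminogen activator inhibitor, at 30.8 and 220 CPM, Serpinb2 at 12 and 360 CPM and coagulation factor F5 at 6.99 and 129 CPM, whereas Procr, the protein C receptor, was 2.44 times as high with the combination. In the alternative activation list 5 of 14 were lower and 1 higher (median -0.22, percentile 0.47), but the median lay outside its random range in only 12 of 17 settings, and under the stricter hashtag rule 3 were higher and 5 lower. The arginase gene Arg1, a marker of macrophages that suppress T cells, was at 1513 and 4106 CPM, Chil3 at 314 and 1627 CPM, Retnla at 9.83 and 94.1 CPM and the eosinophil chemokine gene Ccl24 at 54.3 and 222 CPM, and Clec10a was the higher member, with a ratio of 1.5 (1.41 without cluster 0). Serpinb2 was a leading gene of cluster 0, and without that cluster the PBS cells were at 54.2 CPM for Serpinb2, 45.2 CPM for F5 and 717 CPM for Chil3.

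Chemokine genes went both ways, with 8 of 21 higher and 8 lower (median -0.40). Cxcl9 and Cxcl10, which recruit T cells and are induced by IFNg, were at 917 and 458 CPM and at 165 and 95.2 CPM. Ccl8 was 1.75 times as high and Ccl5 2.69 times as high with the combination, while Ccl6 (1360 and 2734 CPM) and the neutrophil chemokine gene Cxcl3 (42.5 and 144 CPM) were lower. Without cluster 0, 4 chemokine genes were higher and 10 lower, and Ccl8 was at 1.38. Under the stricter hashtag rule, Cxcl9 was at a ratio of 1.37, Cxcl3 turned to 1.45 (1.21 to 1.74) and the chemokine median to 0.41. Transcripts of the cytotoxic effector list, to which Ccl5 belongs, were also higher in these cells, in 9 of 10 measured genes. RNA of T cells in these droplets may therefore add to the Ccl5 ratio, which was not tested. The dectin-1 and NF-kB inflammatory list had 3 of 22 genes higher and 7 lower (median -0.04, percentile 16.4). Among them, Il1b had a ratio of 0.59, Il6 0.27 and Tnf 2.06. Under the stricter rule Il1b turned to 2.15 (1.83 to 2.55), and this list to a median of 0.53 with 9 genes higher and 3 lower.

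The lipid-associated macrophage list had 7 of 15 genes higher and 3 lower (median 0.43, above all random lists). Gpnmb, a lysosomal membrane protein of lipid-loaded macrophages, was at 118 and 27.8 CPM, and the lipid receptor gene Trem2 at 222 and 128 CPM. Spp1, which encodes osteopontin, was lower, at 326 and 821 CPM, with a ratio of 0.40, and 0.81 under the stricter hashtag rule. The protease gene Ctsk had a ratio of 12.7 with the cell filter and 0.238 without it. Fkbp5 (5.86), the proton pump gene Atp6v0d2 (4.76) and Ly6i (4.30) were among the 10 named genes with the highest ratios. In the MHC class II list 5 of 12 genes were higher and 0 lower (median 0.44, percentile 99.96), and without cluster 0 only 1 was higher, with a median of 0.21. Trem2 had a ratio of 1.73, and 1.44 without cluster 0.

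The IFN-gamma response list moved little in macrophage-like cells. Of 28 genes, 2 were at least 1.5-fold higher and 1 lower, the median was 0.12, and the transcription factor gene Stat1 had a ratio of 1.17. The higher genes were Cxcl9 and Cxcl10, and the lower was Wars (0.54). Without cluster 0, however, Cxcl10 (1.38) and Wars (0.73) did not pass 1.5-fold, and the list had 1 gene higher and 2 lower. The type I interferon list had 5 of 17 genes higher, among them Rsad2 (2.01) and Ifit1 (2.03), whose ratios ranged from 1.005 to 2.14 and from 1.19 to 2.17 over the settings and were 14.4 and 4.33 under the stricter hashtag rule, and 3 lower, with a median of 0.30 that turned to -0.16 when each cell went to its larger hashtag, and without cluster 0 it had 6 higher and 0 lower. MHC class I processing genes had a median of 0.10 with 0 of 13 past 1.5-fold. The complement and phagocytosis list had 4 of 18 higher, among them the engulfment receptor genes Mertk (1.52) and Stab1 (1.87), and 4 lower, among them the integrin gene Itgam (0.50). Without cluster 0 it had 4 higher and 0 lower, with Itgam at 0.69 and Mertk at 1.49. Its member C1qa had a ratio of 1.42. Cell cycle genes had 4 of 20 higher and 0 lower (median 0.17, and -0.06 without cluster 0), but 13 of 17 were higher under the stricter hashtag rule (median 0.78). The median was -0.12 for dissociation stress genes, with Hspa8 at a ratio of 1.68, and 0.24 for mitochondrially encoded genes, with 0 of 13 past 1.5-fold. Of the genes that differ between female and male animals, only Xist (680 and 644 CPM) and Tsix (35.3 and 33.4 CPM) reached 50 counts.

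**Figure D3:**
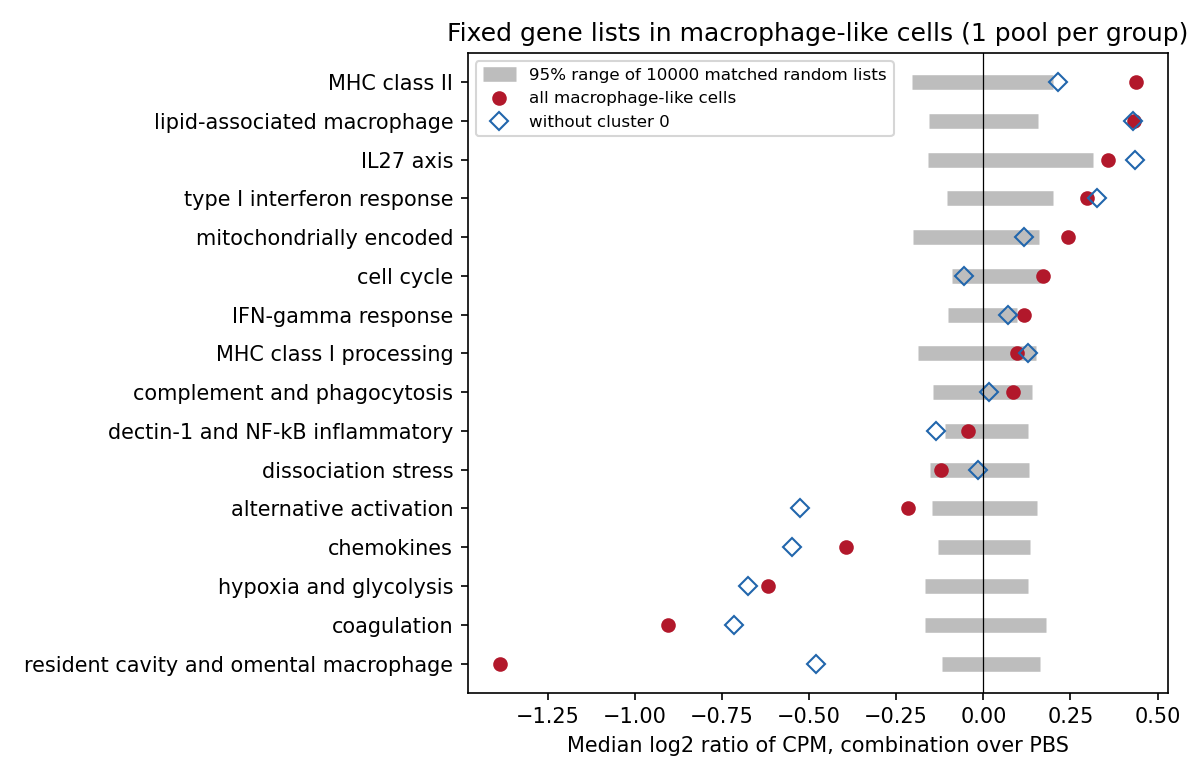
Median log2 ratio of CPM, combination over PBS, for 16 gene lists in macrophage-like cells, over all cells of the class (red circles) and without cluster 0 (open blue diamonds), with grey bars for the 95% range of 10000 matched random lists. The resident list lay at -1.39 and at -0.48 without cluster 0, whereas the hypoxia and glycolysis list lay at -0.62 and -0.67 and the lipid-associated list at 0.43 both ways.

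In neutrophil-like cells, genes of the cell cycle were higher with the combination, and genes of hypoxia were lower. Among the 10 named genes with the highest ratios, the granule enzyme gene Mpo was at 63.4 CPM (54.4 to 73.5) with the combination and 1.75 CPM (0.478 to 4.49) with PBS, the elastase gene Elane at 174 and 18.9 CPM, Fcnb at 142 and 33.3 CPM, and Ly6g, a surface marker of neutrophils, at 215 and 48.7 CPM. Orm1 had a ratio of 13.1, which ranged from 2.71 to 23.4 over the settings and was 2.91 under the stricter hashtag rule (17 and 6 UMIs). Few cells carried the first 2 of these, with Mpo detected in 5.66% and 0.481% of the cells and Elane in 6.92% and 0.962%, and their ratios ranged over the settings from 1.28 to 66.5 for Mpo and from 1.72 to 17.3 for Elane. In the cell cycle list 17 of 19 genes were higher and 0 lower (median 1.14, above all random lists), with Mki67 at 137 and 62.2 CPM, Top2a at a ratio of 2.72 and Stmn1 at 2.94. The class held 159 combination cells (median 13471 UMIs) and 208 PBS cells (median 8711). These were a minority, since the hashtag rule called only 19.4% of the neutrophil-like cells of the pair. The pools lay in another mix of clusters. Cluster 17, led by chemokine genes, was the largest in both, with 74 combination cells and 174 PBS cells, and cluster 7, led by granule genes, held 73 and 21. Within cluster 17 the ratio of Ly6g was 1.15 (0.603 to 2.09), so its difference over the class may follow the mix.

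The hypoxia and glycolysis list had 8 of 14 genes lower and 0 higher in neutrophil-like cells (median -1.03, below all random lists). Egln3 was at 392 and 1361 CPM, and the ratio was 0.30 for the mitophagy gene Bnip3, 0.30 for the glycolytic enzyme gene Pfkp and 0.215 for the lipid droplet gene Hilpda. Within cluster 17 the ratios of Bnip3, Pfkp and Hilpda were 0.58, 0.45 and 0.52. The dectin-1 and NF-kB inflammatory list had 9 of 19 genes lower and 0 higher (median -0.55, percentile 0.70), but lay outside its random range in only 12 of 16 settings, and not with doublets kept, the larger hashtag, each cell counted alike or thinned cells, nor under the stricter hashtag rule. The inflammatory cytokine gene Il1b was at 1608 and 4300 CPM, the chemokine gene Cxcl2 at 4291 and 8613 CPM, and Ccl3 had a ratio of 0.52. Cxcl2, Ccl3 and Egr1 were among the leading genes of cluster 17, and within it the ratios of Cxcl2 and Ccl3 were 0.99 and 1.08, whereas those of Il1b and Egln3 were 0.70 and 0.53. Hbegf and Spp1 had ratios of 0.223 and 0.249. In the dissociation stress list, which reports handling of cells as well as activation, 11 of 16 were lower, among them Egr1 (0.50) and Jun (0.53), which were at 0.77 and 0.67 within cluster 17.

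IFN-gamma response genes went both ways in neutrophil-like cells, with 6 of 24 higher and 7 lower (median -0.19, percentile 43.4). Cxcl9 was at 130 and 24.1 CPM, whereas Gbp2, a GTPase, and Cd274, which encodes PD-L1, had ratios of 0.55 and 0.50 over the class but 0.91 (0.816 to 1.01) and 0.95 (0.872 to 1.03) within cluster 17. The ratio of Cxcl9 ranged from 1.97 to 6.85 over the settings. Within cluster 17 it was 14.6, with Cxcl9 detected in only 16.2% and 9.77% of the cells. Iigp1 had a ratio of 3.59, and 0.531 after removal of the highest 7% of Scrublet scores. In the MHC class II list 5 of 9 genes were higher (median 0.77), with ratios of 2.52 for H2-Ab1, 3.08 for H2-Eb1 and 1.70 for Cd74, but the median was 0.13 after that removal and 0.02 with the larger hashtag. Under the stricter hashtag rule (24 and 31 cells) it turned to -0.33, with H2-Ab1 at 0.92, H2-Eb1 at 1.23 and Cd74 at 0.72 (0.614 to 0.849). Within cluster 17 the ratios were 4.38 for H2-Ab1, 5.12 for H2-Eb1, 2.58 for Cd74 and 4.31 for Iigp1. H2-Ab1 was detected in 45.9% and 39.1% of the cells there. The type I interferon list had a median of -0.36 (percentile 6.13). Of 5349 genes with at least 100 counts, 462 were at least 1.5-fold higher and 888 lower, and this split depended on scaling, at 582 and 686 with TMM and 568 and 636 with each cell counted alike.

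Over all T cell-like cells, genes of regulatory T cells, which restrain other T cells, were higher with the combination. Foxp3, the transcription factor that defines regulatory T cells, was at 68.2 CPM (62.5 to 74.3) with the combination and 37.4 CPM (33.3 to 41.9) with PBS, and Il2ra, their IL2 receptor chain, at 164 and 94.2 CPM. Under the stricter hashtag rule, which left 29 and 21 of these cells, Il2ra turned to a ratio of 0.60 (0.47 to 0.762), and the regulatory list had 4 genes higher and 3 lower, with a median of 0.25 inside its random range. In the regulatory T cell list 6 of 15 genes were higher and 1 lower (median 0.51, above all random lists), with Lrrc32 at a ratio of 2.30 and Areg at 2.04. The lower member was Il10 (0.42, from 26 and 64 counts). Areg and Il10 changed direction in cells thinned to 1000 UMIs. The cytotoxic effector list had 2 of 15 genes higher and 1 lower, with a median of -0.26, below all random lists. Gzma, which encodes a granzyme, was at 57.2 and 95 CPM. Gzmb had a ratio of 1.16, Ccl5 0.71, Klrg1 1.57 and Ifng 1.11. Under the stricter rule Gzma turned to 11.9 (36 UMIs and 1 UMI), Ccl5 to 3.01 and Ifng to 0.0871, so no direction is claimed for these genes. The class held 647 combination cells (median 9581 UMIs, 7729613 in all) and 727 PBS cells (median 9415, 7939748 in all). The pools lay in another mix of T cell clusters, so these differences may reflect the mix and not a change within cells. Cluster 11, led by Foxp3 and other regulatory genes, held 173 and 99 cells, whereas cluster 16, led by Cd8a, held 173 and 233, cluster 23, led by Klra7, 87 and 129, and cluster 25, with Ifng and Xcl1 among its leading genes, 54 and 112.

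In the naive and memory list 2 of 10 genes were higher and 0 lower (median 0.21). These were Il7r, the IL7 receptor chain, at 356 and 168 CPM, and Klf2, a transcription factor of resting T cells, with a ratio of 2.28. The inhibitory receptor list had 1 of 12 genes lower, Cd160 (0.58), and a median of 0.05, with Pdcd1, which encodes PD-1, at 1.23. The helper cytokine list had a median of 0.04, with Csf2 at 0.51. The cell cycle list had 0 of 20 genes past 1.5-fold. The hypoxia and glycolysis list had 0 of 13 (median -0.12). The IFN-gamma response list had 5 of 27 genes higher and 0 lower (median 0.31, above all random lists), with Iigp1, a GTPase, at 90.7 and 48.4 CPM. The other 4 higher members are genes expressed mainly by macrophages and other antigen-presenting cells. Early response genes of the dissociation stress list were higher in 8 of 16 and lower in 0 (median 0.58), with Fos at 3.69, Fosb at 4.41 and the heat shock gene Hspa1a at 0.75. The NK receptor genes Klra1 and Klra7 (both 0.467), Gpm6b (0.466) and Sema6d (0.401) were among the 10 named genes with the lowest ratios. Klra1 and Klra7 lead cluster 23 and Gpm6b is a leading gene of cluster 25, which both held fewer combination cells, so their ratios may follow the mix of clusters. Of 9171 genes, 310 were at least 1.5-fold higher and 100 lower.

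Macrophage transcripts were found in T cell-like cells at different levels in the pools. The complement and phagocytosis list had 12 of 14 genes higher and 0 lower with the combination (median 1.28). Lyz2 was at 392 and 90 CPM, Apoe at 326 and 74.9 CPM, Mafb at 22.4 and 3.78 CPM, Mrc1 at 31.6 and 5.92 CPM, and C1qa at 63.5 and 21.5 CPM. Spp1, in contrast, was at 34.7 and 124 CPM. After removal of the highest 7% of Scrublet scores the list's median was 0.21, and 175 genes in place of 310 were at least 1.5-fold higher, whereas the regulatory list stayed at 0.51.

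The genes of IL27, a cytokine made of a p28 chain (Il27) and a chain encoded by Ebi3, were then followed across classes. Il27 did not differ between the pools beyond counting error, at 15.8 CPM (14.0 to 17.7) and 19.0 CPM (16.3 to 21.9) in macrophage-like cells and at 22.9 CPM (17.7 to 29.3) and 23.2 CPM (17.4 to 30.4) in neutrophil-like cells. Ebi3 was higher with the combination in macrophage-like cells, at 19.2 CPM (17.2 to 21.3) and 9.02 CPM (7.24 to 11.1), though its ratio of 2.12 was 1.25 in cells thinned to 1000 UMIs (12 and 6 UMIs) and had an interval of 0.898 to 3.39 under the stricter hashtag rule. Ebi3 stood at 49.4 CPM (41.5 to 58.4) and 36.8 CPM (29.4 to 45.6) in neutrophil-like cells. The receptor gene Il27ra was at 79.7 CPM (73.5 to 86.2) and 86.8 CPM (80.4 to 93.5) in T cell-like cells and at 69.1 and 56.2 CPM in the 40 and 84 NK cell-like cells, against 4.59 and 4.51 CPM in macrophage-like cells. Il12b, which encodes a chain of IL12 and IL23, had 61 UMIs in combination macrophage-like cells and 2 in those of PBS, a ratio with a counting interval of 4.31 to 137. These UMIs lay in 0.681% and 0.364% of the cells, and Il12b is a leading gene of cluster 19, the mature dendritic-like cells, so a few cells of another type may carry it. In the IL27 axis list 6 of 13 genes were higher in macrophage-like cells and 1 lower (median 0.36). That median was -0.27 with members of at least 200 counts only and -0.58 in thinned cells, so the list as a whole had no steady direction.

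Il27 was detected in 22.6% of the combination and 22.0% of the PBS macrophage-like cells, and Ebi3 in 28.4% and 12.2%. In T cell-like cells, which are not a main source of p28, Il27 was detected in 2.63% and 1.79%, at a median depth of 9581 and 9415 UMIs against 20394 and 16882.5. After thinning to 1000 UMIs, Il27 was detected in 1.59% of 881 and 0.911% of 549 macrophage-like cells and in 0 of 647 and 0 of 723 T cell-like cells. The limits of 0.464% and 0.415% on the latter hold for detection at this depth and not for cells that express the gene. Thinning left out 1 PBS macrophage-like cell and 4 PBS T cell-like cells. The thinned shares rest on 14 and 5 cells with a UMI, too few to read a difference between the pools. Il27ra was detected in 54.3% and 54.2% of the T cell-like cells, and in 9.74% and 11.6% after thinning.

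The main genes above are protein-coding in the GRCm38 annotation, and the counts are per gene with no exon or intron given. Il27 (ENSMUSG00000044701) lies on chromosome 7 from 126589010 to 126594941 and Ebi3 (ENSMUSG00000003206) on chromosome 17 from 55952640 to 55957022. Gata6 (ENSMUSG00000005836) lies on chromosome 18 from 11052064 to 11085635, Prg4 (ENSMUSG00000006014) on chromosome 1 from 150449412 to 150466165, and Arg1 (ENSMUSG00000019987) on chromosome 10 from 24915221 to 24927484. Apoe (ENSMUSG00000002985) lies on chromosome 7 from 19696109 to 19699188, Egln3 (ENSMUSG00000035105) on chromosome 12 from 54178981 to 54203860, Mpo (ENSMUSG00000009350) on chromosome 11 from 87793581 to 87804413, and Foxp3 (ENSMUSG00000039521) on chromosome X from 7573644 to 7595245.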

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

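The tests below on macrophage-like and T cell-like cells were chosen after the results were seen, and those on neutrophil-like cells before their results were seen. Hashtag 3 is also named PBS, but it belongs to the other hashtag pair. Its cells were assigned to no treatment and entered no comparison. In 1916 macrophage-like cells of hashtag 3, the genes of the resident cavity and omental macrophage list summed to 9039 CPM. This was 3.73 times the 2425 CPM of the PBS pool, and the combination pool was at 957 CPM. By this sum the hashtags named PBS lay further apart than the compared pools, but single genes went both ways. Prg4 was at 3351 CPM in hashtag 3, 488 CPM in the PBS pool and 6.99 CPM in the combination pool. Its ratio was thus larger between the compared pools. Timd4 was at 152, 25.9 and 10.8 CPM, a larger ratio between the hashtags named PBS. The genes of this list stand out because their summed signal lies in cells that the comparison did not use, above the level of the PBS pool.

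The lower resident and hypoxia genes in macrophage-like cells of the combination pool form the first pattern, though under the stricter hashtag rule only 1 of 14 hypoxia genes was lower (median -0.32). Cluster 0, which held 80 PBS cells and 0 combination cells, is a candidate explanation. Without it the resident list's median stayed at -0.48, below its random range of -0.12 to 0.19, and the hypoxia and glycolysis list's at -0.67, below -0.16 to 0.12, which argues against this cluster as the whole cause, although it held much of the resident difference (-1.39 over all cells). For the hypoxia genes the median was -0.76 (range -0.26 to 0.18) with every cell thinned to 1000 UMIs. Ratios of CPM are already scaled to the total counts. Thinning was therefore unlikely to bring the median into its range, and it does not decide on a difference in depth. A response to the combination stays open, as a hypothesis, and so does a difference between the mice that were pooled. Another mix of macrophage-like cells outside cluster 0 was not tested and stays open too. With doublets kept, a cluster with Vegfa among its leading genes held 242 combination and 281 PBS cells. Another cluster, led by Ccl8, held 598 and 179.

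The higher macrophage transcripts in T cell-like cells of the combination pool form the second pattern. Without the highest 7% of Scrublet scores the median of the complement and phagocytosis list was 0.21 over 11 measured genes (1.28 before), inside its range of -0.17 to 0.23, which is consistent with droplets that held a T cell and a macrophage. That removal would also take out T cells that carried macrophage RNA for another reason, so the origin of the transcripts stays open. The removed cells were 6.49% of the combination T cell-like cells and held 42.8% (41.1 to 44.4) of the list's UMIs there. As many of the highest cells could hold at most 12.4% if free RNA reached all droplets alike. A first bound of 50%, replaced after the value was seen, was not reached. Scrublet picks cells with mixed transcriptomes, so this share does not decide on free RNA. Both pools were in the same library, so free RNA that reached all its droplets alike would give no difference between them. The macrophage-like share was larger in the combination pool, and no biological explanation was tested.

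The higher cell cycle genes and lower hypoxia genes in neutrophil-like cells of the combination pool form the third pattern, and another mix of neutrophil clusters is a candidate explanation. Within cluster 17 the hypoxia and glycolysis list had 4 of 14 genes lower and a median of -0.45, below its range of -0.28 to 0.19, which argues against the mix as the whole cause, although the median over the class was -1.03. For the cell cycle genes the mix cannot be told apart from a change within cells, since cluster 17 had only 4 measured genes (median 0.01, range -0.44 to 0.37). A response to the combination stays open, as an untested hypothesis.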

How the results depend on the processing

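The alternatives chosen only after the data were seen were the larger hashtag, the pair of hashtags 8 and 9 clustered alone, the removal of high Scrublet scores and the removal of cluster 0. No paired analysis was possible because each group was 1 pool of mice that the hashtags do not tell apart. For the same reason DESeq2, leaving out each mouse and other splits of the samples were not run. Of 509 list medians under an alternative, 441 moved by no more than 0.5 of the width of the random range, 61 moved further and 7 reversed. Of 59 differences of shares, 46 stayed within their interval, 7 left it and 6 reversed. Of 86 counts of genes, 73 stayed within 1.5 times the main count. Of 1592 ratios of named genes, 1155 stayed within their interval, 431 left it and 6 reversed. A result counts as reversed only where the main value was clear of no difference, by the interval for a share, the random range for a list, and the interval and 1.5-fold for a gene. With no such condition, 19 ratios of genes lay on the other side of 1, and the other 13 were of Il27, Ebi3, Il27ra and Ifng. In all 17 settings with a value, the main one included, the macrophage medians kept their direction for the resident list (-1.56 to -0.48), hypoxia and glycolysis (-0.76 to -0.59), coagulation (-1.01 to -0.67), lipid-associated (0.16 to 0.52) and MHC class II (0.21 to 0.62). The IFN-gamma list in macrophage-like cells lay outside the random range in 9 of those settings. In T cell-like cells the regulatory list ranged from 0.30 to 0.52, and in neutrophil-like cells hypoxia and glycolysis from -1.04 to -0.54 and the cell cycle list from 0.51 to 1.43, over 16, 16 and 15 settings. Values below are combination minus PBS in percentage points for shares, median log2 ratios for lists, and ratios of CPM for genes.

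With the larger hashtag the differences of shares were 5.65 for macrophage-like cells, 1.86 for T cell-like, 0.31 for neutrophil-like, -2.98 for monocyte-like, 0.039 for NK cell-like and -1.54 for plasma cell-like cells, so those of T cell-like, neutrophil-like and NK cell-like cells reversed. The macrophage medians were -0.155 for type I interferon (reversed), -0.008 for chemokines, 0.45 for cell cycle and -0.28 for dissociation stress. MHC class II in neutrophil-like cells was 0.024. The T cell medians were 0.504 for complement and phagocytosis, 0.462 for naive and memory, 0.321 for regulatory, -0.184 for cell cycle and 0.445 for dissociation stress. With doublets kept the shares differed by 11.7 (macrophage-like), 0.447 (T cell-like, reversed) and -2.86 (monocyte-like), and 722 genes were higher in neutrophil-like cells. The macrophage medians were -0.195 for type I interferon (reversed), -0.208 for dectin-1 and NF-kB, -0.241 for chemokines and 0.328 for cell cycle. The median was 1.16 for MHC class II in neutrophil-like cells, and in T cell-like cells 0.532 for complement and phagocytosis, 0.431 for naive and memory and -0.108 for cell cycle.

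The stricter hashtag rule left 97 and 80 macrophage-like, 24 and 31 neutrophil-like and 29 and 21 T cell-like cells, under the minimum of 100, because few cells had 90% of 1 hashtag. Shares then differed by 4.15 (macrophage-like), 3.11 (T cell-like, reversed), -6.16 (neutrophil-like) and 1.71 (monocyte-like, reversed). Expression in so few cells was used only as a check on the main values. The medians there were -1.14 for the resident list, -0.32 for hypoxia and glycolysis (1 of 14 lower), 0.78 for cell cycle, 0.41 for chemokines and 0.53 for dectin-1 and NF-kB in macrophage-like cells. Of 33 list medians 8 turned, namely these last 2 and IL27 axis (-0.001) in macrophage-like cells, MHC class II (-0.33), type I interferon (0.19) and IFN-gamma response (0.02) in neutrophil-like cells, and inhibitory receptors (-0.73) and helper cytokines (-0.33) in T cell-like cells. The regulatory list was at 0.25, inside its random range of -0.32 to 0.42. Of 115 ratios of named genes, 17 turned. The 8 whose interval then left out 1 were Il1b (2.15) and Cxcl3 (1.45) in macrophage-like cells, Cd74 (0.72) in neutrophil-like cells, and Pdcd1 (0.65), Il2ra (0.60), Ifng (0.0871), Ccl5 (3.01) and Gzma (11.9) in T cell-like cells. The other 9 were Clec10a (0.90) in macrophage-like cells, Il27 (1.31), H2-Ab1 (0.92) and Iigp1 (0.77) in neutrophil-like cells, and Il10 (1.33), Sema6d (1.66), Cd160 (1.24), Lrrc32 (0.996) and Il27ra (1.58) in T cell-like cells. These intervals treat UMIs of the same cell as independent, so they do not mark the 8 as clear reversals. For Gzma, 36 UMIs lay in 6.9% of the 29 combination T cell-like cells.

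Without the highest 7% of Scrublet scores 175 genes were higher in T cell-like cells. The medians were -0.078 for type I interferon in macrophage-like cells (reversed), 0.126 for MHC class II and 0.807 for cell cycle in neutrophil-like cells, and 0.203 for IFN-gamma response, 0.207 for complement and phagocytosis and -0.227 for hypoxia and glycolysis in T cell-like cells. Iigp1 in neutrophil-like cells reversed to 0.531. Without cluster 0 the macrophage medians were 0.214 for MHC class II, -0.526 for alternative activation, -0.481 for resident, -0.715 for coagulation, -0.548 for chemokines and -0.055 for cell cycle (reversed), and Timd4 reversed to 2.84. With the pair clustered alone they were 0.013 for type I interferon and, in T cell-like cells, 1.53 for complement and phagocytosis.

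Cells thinned to 1000 UMIs keep few counts per gene. There 132 genes were higher and 229 lower in macrophage-like cells, 59 and 135 in neutrophil-like and 61 and 35 in T cell-like cells. The macrophage medians were -0.017 for IFN-gamma response (reversed), 0.093 for type I interferon, -0.583 for the IL27 axis (reversed), -0.435 for dectin-1 and NF-kB, -0.586 for alternative activation, -0.972 for resident, 0.163 for lipid-associated and -0.673 for coagulation. In neutrophil-like cells they were 1.19 for MHC class II and -0.233 for dectin-1 and NF-kB, and in T cell-like cells 0.177 for IFN-gamma response, 0.268 for inhibitory receptors and 0.301 for regulatory. The ratio reversed to 0.623 for Il12b in macrophage-like cells and to 1.12 for Il10 and 0.447 for Areg in T cell-like cells. A minimum of 300 counts gave 299 genes higher in macrophage-like, 194 higher and 510 lower in neutrophil-like, and 104 higher and 28 lower in T cell-like cells, since fewer genes entered.

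With each cell counted alike the macrophage medians were -0.377 for alternative activation and -0.594 for chemokines. In neutrophil-like cells they were -0.222 for dectin-1 and NF-kB and -0.542 for hypoxia and glycolysis, and in T cell-like cells 0.205 for IFN-gamma response, 0.725 for complement and phagocytosis and 0.254 for inhibitory receptors. At resolution 2.0 the macrophage medians were 0.067 for type I interferon, -0.057 for alternative activation and -0.054 for chemokines, and at 0.5 the T cell median was 0.222 for IFN-gamma response. Clustering without interferon and MHC genes gave 0.075 for type I interferon, -0.074 for chemokines and 0.379 for cell cycle in macrophage-like cells and 0.509 for cell cycle in neutrophil-like cells. The stricter cell filter gave 0.071 for type I interferon and -1.56 for resident in macrophage-like cells and 0.921 for complement and phagocytosis in T cell-like cells. With no cell filter these were 0.202 for lipid-associated in macrophage-like cells and 1.09 for complement and phagocytosis in T cell-like cells, and Ctsk reversed to 0.238. Members with at least 200 counts gave -0.265 for the macrophage IL27 axis (reversed) and 1.49 for complement and phagocytosis in T cell-like cells, and those with at least 10 gave -0.224 for helper cytokines. TMM scaling and totals without mitochondrial and ribosomal genes reversed nothing and moved no list median or count of genes past its bounds, but put the ratios of 13 and 2 named genes with high counts, such as Apoe in macrophage-like cells, just outside their narrow intervals.

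The share of cells with a UMI follows depth. With no thinning it was 22.6% and 22.0% for Il27 and 28.4% and 12.2% for Ebi3 in combination and PBS macrophage-like cells, and 24.5% and 19.2% for Il27 and 44.7% and 30.3% for Ebi3 in neutrophil-like cells. Thinned to 2000 UMIs it was 3.53% and 3.68% for Il27 and 3.76% and 0.921% for Ebi3 in combination and PBS macrophage-like cells, and in neutrophil-like cells 7.05% for Il27 (combination) and 7.69% and 8% for Ebi3. Apart from the numbers of cells, counts and genes named above, the cause was not tested.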

Other observations

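No test is reported in this part. The cells of hashtags 3 and 5, which were assigned to no treatment, differed in makeup from each other. Of 6074 cells of hashtag 3, 31.5% were macrophage-like, 24.0% neutrophil-like, 19.2% monocyte-like and 14.6% T cell-like. Of 6227 cells of hashtag 5, 54.4% were macrophage-like, 19.4% T cell-like, 6.65% monocyte-like and 3.10% neutrophil-like. Plasma cell-like cells numbered 4 in hashtag 3 and 1 in hashtag 5, against 51 in hashtag 8 and 107 in hashtag 9.

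Macrophage-like cells of these hashtags carried different programmes. Prg4 was at 3351 CPM in hashtag 3 and 844 CPM in hashtag 5, Alox15 at 2438 and 405 CPM, and Gata6 at 140 and 31.4 CPM. Arg1 was at 5625 and 1485 CPM and Chil3 at 1674 and 160 CPM. Apoe, in contrast, was at 1155 CPM in hashtag 3 and 13918 CPM in hashtag 5, and Mertk at 224 and 625 CPM. Cxcl9 was at 23.9 and 24.9 CPM, below its level in either pool of the comparison (917 and 458 CPM), and Gpnmb at 4.99 and 3.38 CPM. Cluster 0 held 975 cells of hashtag 3, 7 of hashtag 5, 0 of hashtag 8 and 80 of hashtag 9. Median depth in macrophage-like cells was 19292 UMIs for hashtag 3 and 8744 for hashtag 5.

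Spp1, which encodes osteopontin, had a ratio of 0.40 in macrophage-like, 0.249 in neutrophil-like and 0.28 in T cell-like cells. It was 0.807 in macrophage-like cells under the stricter hashtag rule, and in neutrophil-like cells 0.727 after thinning to 1000 UMIs and 0.586 within cluster 17. T cell-like cells can hold Spp1 RNA from other cells.

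Genes of T cells were found in macrophage-like cells. There the list medians were 0.91 for cytotoxic effectors (9 of 10 higher), 0.53 for inhibitory receptors (5 of 11 higher, 1 lower), 0.65 for regulatory T cells (5 of 9 higher) and 0.68 for helper cytokines (3 of 5 higher). In T cell-like cells, MHC class II genes, most of which mouse T cells do not express, were higher in 6 of 10 and lower in 1 (median 0.71).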
